A study of Pan troglodytes with 4 samples.

How the data were processed

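The series holds 4 two-colour arrays of spotted human cDNA clones. Each array was hybridised with RNA of biopsies of 1 chimpanzee (animal 190), taken 19, 20, 21 and 32 weeks after infection and set against a baseline biopsy, with 1 array per week. The labels name neither the tissue nor the infecting agent. Per the labels' protocols, total RNA was extracted with Trizol, its mRNA was amplified with an Arcturus kit, and the RNA was labelled with Cy5 or Cy3 with a Perkin Elmer kit. All 4 arrays carry the same dye labels, which name no dye swap. The labels do not state which dye holds the baseline RNA. Every direction is therefore given as Cy5 over Cy3, and if the Cy5 channel holds the baseline, each sign turns for the change after infection. The ratio keeps the spread of the baseline biopsy itself and any dye preference of a single probe. Both cancel in a difference between arrays if the arrays share the baseline RNA and the dye orientation.

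The deposited spot intensity of each channel was read from the sample files, where red was taken as Cy5 and green as Cy3. Values have a floor of 1, and no background column was used here, so the deposited intensities were taken as already corrected and no further background correction was made in the main setting. The design fixed before the data were examined had allowed for this case. The deposited quality score of a spot runs from 0 to 1, its definition is not given in the sources used here, and spots with a score of 0 were left out. The log2 ratio that the authors deposited, in the sample files and in the series matrix, equals the log2 of the unnormalised intensities. The ratio of the sample files equals the log2 of the intensities within 1e-06, and the series matrix equals that ratio within 1e-06, each for 8258 to 8259 of the 8259 spots of an array. Its median was -0.41, -0.66, -0.49 and 0.05 on the arrays of weeks 19, 20, 21 and 32, so it is on a log2 scale, Cy5 over Cy3, and not centred. In the week 19 file a first column of plate positions matched the second one at 3 of 8259 spots. The second column, identical in all 4 files, was used to name spots.

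Spots without a clone identifier (200 per array) were left out. The array has 78 plates of single-copy clones and 8 plates that carry the same 88 clones, most of them in 8 copies, which were averaged. On 4 single-copy plates most spots had a quality score of 0 on all arrays. Probes with a value on at least 3 arrays were tested, which left 6697, of which 6488 had a value on all 4. Gene symbols are those of the array's files, and 6179 of the tested probes carried 1 plain symbol, giving 6021 different symbols. Of these, 4070 are symbols of the chimpanzee RefSeq annotation, and the others were kept as the files give them. No plain symbol was held by 518 probes, and 2 symbols of the array had been turned into calendar dates by a spreadsheet and were not used. More than 1 probe was present for 150 symbols.

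Ratios were normalised within each array with a global loess (limma 3.58.1 in R 4.3.3). The log2 ratio of each probe was tested against 0 over the 4 arrays with lmFit and eBayes in limma, with Benjamini-Hochberg adjustment and a threshold of 0.05. A second fit set week 32 against the mean of weeks 19, 20 and 21. The single week 32 array was assumed to vary like the other arrays. The 4 arrays are biopsies of 1 animal, so p-values measure the spread between these biopsies and arrays, which may in part be technical, and not the spread between animals. Gene lists were tested with camera in limma at a preset correlation of 0.01, and beside it with an estimated correlation and with fry. The 37 lists of interferon, immune, liver, other tissue and stress genes had been fixed before the data were examined, each gene stood for 1 probe (the one with the highest mean intensity), and a list needed 5 measured members. Single arrays have no test: the number of probes with an absolute log2 ratio of at least 1 and the median of each list were given, the latter with its percentile among 10000 random lists matched on intensity.

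Genes were named by a rule fixed in advance. It took the 10 genes with the largest mean ratio in each direction that passed the test, had the same sign on all 4 arrays and a mean intensity above the median. For week 32 it took up to 5 genes per direction with the smallest p. It also took up to 4 members of each called list in the list's direction and 2 against it, the 6 interferon-stimulated genes with the smallest p, and the gene with the largest ratio on each array. Of the genes this rule took, 2 are not reported here and were not replaced. Other genes are said to be chosen after their values were seen.

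The steps were tested on simulated data of these probes with 200 changed probes. In the comparison of the channels over 6697 probes, 10.4% of the probes changed by a log2 ratio of 0.5, 80.6% of those changed by 1 and 100% of those changed by 2 were recovered, with 5 false calls. In the comparison of week 32 with the earlier weeks over 6631 probes, 0 of 67, 0 of 67 and 0 of 66 were recovered at these sizes, so that fit cannot be expected to call single probes. A simulated shift of the interferon-stimulated list by 0.5 at week 32 was called by camera, with an adjusted p of 2.35e-07 and 0 other lists called. The simulated noise was drawn independently for each probe. In the data the estimated correlation within this list was 0.58 for week 32 against weeks 19 to 21. The simulation therefore does not show how camera behaves with members that vary together.

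Alternatives fixed in advance were normexp with offsets of 0 and 16, median centring, scale normalisation between arrays, the series matrix values, filters on quality and intensity, a trended and robust variance prior, array weights, spots of score 0 kept, a minimum log2 change of 0.5, a slope over weeks, the estimated correlation, the mean of all probes of a gene, and each array left out in turn. Print-tip loess was not run. Normexp with an offset of 50, the fits without the 8 repeated-clone plates, and camera for each week against the other 3 were added after seeing the data.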

Results

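RNA of biopsies of 1 chimpanzee was measured on 4 two-colour cDNA arrays, 1 each for weeks 19, 20, 21 and 32 after infection, a stage the labels call acute infection. The series compared a baseline biopsy with the biopsies taken after infection. Each array held 8259 spots, of which 882, 828, 900 and 887 had a quality score of 0 at weeks 19, 20, 21 and 32. The median intensity of the other spots was 156.1, 271.8, 177.9 and 257.2 in Cy5 and 220.4, 443.3, 281.7 and 231.25 in Cy3. Copies of 1 clone on 1 array differed by a median SD of 0.20, 0.15, 0.15 and 0.11 in log2 ratio. The number of arrays limits the precision. All ratios are Cy5 over Cy3 on the log2 scale, since the dye of the baseline RNA was not settled.

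The first comparison asked which genes differed between the 2 RNAs of an array over the whole time course. The largest ratios toward Cy5 were those of RPS4Y, the Y-linked gene of a ribosomal protein, and of metallothioneins, which bind zinc and copper. The largest ratios toward Cy3 were those of VTN and ITIH2, liver-secreted plasma proteins, and of the muscle enolase ENO3. RPS4Y had a mean log2 ratio of 3.36 ± 0.33 (SD, n = 4 arrays; limma adjusted p = 0.00040). MT1L stood at 2.86 ± 0.58, MT1G at 2.67 ± 0.12 and MT1H at 1.89 ± 0.94, and MT1E lay between 1.79 and 3.35 on the arrays. HBB, the beta chain of adult hemoglobin, had a mean of 2.03 ± 0.15 (limma adjusted p = 0.0012), and GLO1, a glyoxalase that detoxifies methylglyoxal, a mean of 2.40 ± 0.35. REL, an NF-kappaB subunit, was at 2.36 ± 0.75, the cytokine CTF1 at 1.96 ± 0.85 and CYR61, a matricellular protein, at 1.65 ± 0.63. A second probe of REL disagreed, with a mean of -0.01. The clone of REL lay in the well beside MT1L and that of CTF1 beside MT1E, with ratio profiles that differed by a root mean square of 0.55 and 0.58 in log2. HBB lay beside F2RL1 (0.55), and MT1L also beside ZFP92 (0.55), which had a mean of 2.32. ZFP92 in turn lay beside FYN (0.17) and FYN beside AGA (0.26). The ratios of all these genes, MT1L and MT1E among them, may therefore in part belong to a neighbour.

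VTN, the plasma protein vitronectin, was brighter in Cy3, with a mean log2 ratio of -3.20 ± 0.67 (SD, n = 4 arrays; limma adjusted p = 0.0032). ITIH2, a heavy chain of an inter-alpha-trypsin inhibitor, had a mean of -2.69 ± 1.33, the insulin-like growth factor binding protein IGFBP1 a mean of -2.57 ± 1.38, and PZP, a protease inhibitor of plasma, a mean of -2.55 ± 0.64. ENO3 stood at -2.63 ± 0.44, VIL1, an actin-binding protein of microvilli, at -2.51 ± 0.46, and EIF5A, a translation factor, at -2.12 ± 0.42. MTHFD1 of folate metabolism was at -2.49 ± 0.63, APOA1, the main protein of high-density lipoprotein, at -2.46 ± 0.79, and the macrophage receptor MARCO at -2.35 ± 0.73. These last 3 clones lay in neighbouring wells of 1 plate, and their ratio profiles over the arrays lay within 0.39 (MTHFD1 and APOA1) and 0.28 (APOA1 and MARCO) of each other, as a root mean square log2 difference. All 20 genes passed the test and had the same sign on all 4 arrays. Many of their clones lay in plate column 11 or 12. Toward Cy3 these were ITIH2, ENO3, IGFBP1, PZP, MTHFD1, APOA1, MARCO and EIF5A. Toward Cy5 they were MT1E, GLO1, CTF1 and MT1H, and the others lay elsewhere. Whether the plate position contributes to these ratios was not tested.

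In all, 927 of 6697 probes passed the limma test at an adjusted p of 0.05. Of these, 427 were brighter in Cy5 and 500 in Cy3, 914 had the same sign on all 4 arrays, and 208 had a mean ratio of at least 2-fold. The count depended on single arrays: it was 33 without week 19, 163 without week 20, 1736 without week 21 and 314 without week 32. It was 1944 with array weights, 42 against a minimum log2 change of 0.5 and 0 with the uncentred series matrix values.

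**Figure D1:**
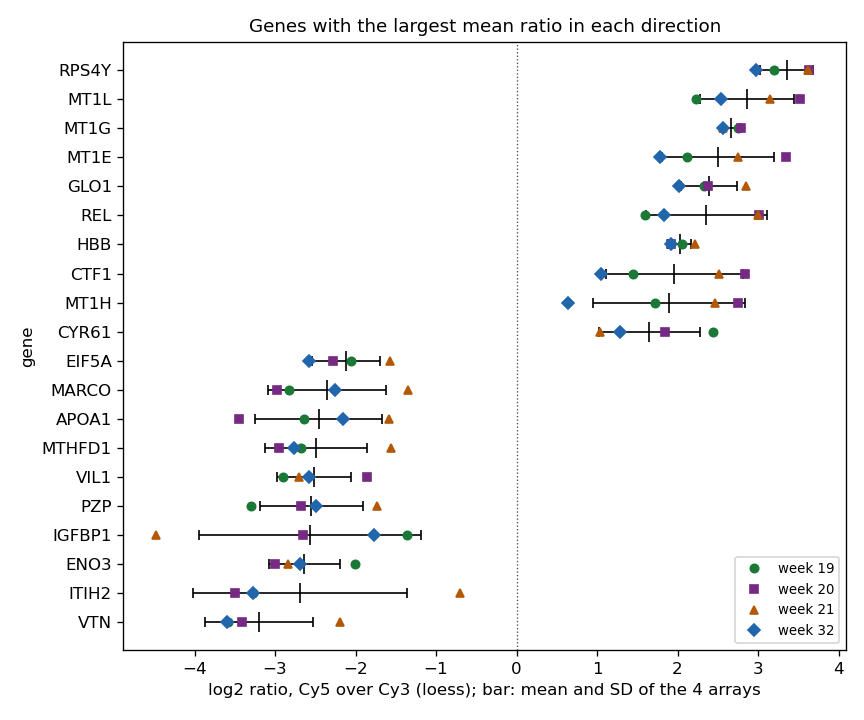
Log2 ratio of Cy5 over Cy3 (x axis) of the 20 genes with the largest mean ratios (y axis); coloured symbols are the 4 arrays, and the bar is the mean and SD over them. RPS4Y lies between 2.97 and 3.63 on all arrays, and ITIH2 lies at -0.70 at week 21 and between -3.50 and -3.27 on the other arrays.

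Among gene groups, cytosolic ribosomal proteins and markers of NK and cytotoxic cells were shifted toward Cy5, while liver-secreted proteins and enzymes of fatty acid oxidation and ketogenesis were shifted toward Cy3. These calls hold with the preset correlation of camera, and with an estimated one 0 lists passed (adjusted p = 0.48 for each of these 4). Of 52 ribosomal protein genes, 25 were brighter in Cy5 and 3 in Cy3 (28 and 4 adjusted over the list alone), with a median log2 ratio of 0.47. The median was 0.30 without the repeated-clone plates (an alternative added after seeing the data) and 0 with the series matrix values, which are not centred, and at week 19 it went from 0.33 to 0.005 with median centring. Beside RPS4Y, the leading members were RPS20 with 1.51 ± 0.37, RPL44 with 1.21 ± 0.33 and RPL31 with 1.14 ± 0.30 (SD, n = 4 arrays). RPL38 went the other way with -1.04 ± 0.57 on 1 probe and 0.51 on a second one that did not pass, and RPL27A had a mean of -0.96 ± 0.88 and did not pass. Of 10 NK and cytotoxic cell markers, 4 were brighter in Cy5 and 1 in Cy3 (7 and 1 adjusted over the list alone), with a median of 0.59. With the series matrix values, which are not centred, the median of this list was 0.19, 0.20, -0.13 and 0.37 at weeks 19, 20, 21 and 32. The lectin receptor KLRB1 stood at 1.28 ± 0.44, the granzyme GZMK at 0.84 ± 0.05 and GNLY, the granule protein granulysin, at 0.75 ± 0.07. GZMA had a mean of 1.13 ± 1.17 and did not pass, and the chemokine gene listed as SCYA4 (now CCL4) was brighter in Cy3 with -1.06 ± 0.51.

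Of 26 liver-secreted protein genes, 9 were brighter in Cy3 and 5 in Cy5 (13 and 5 adjusted over the list alone), with a median log2 ratio of -0.45. VTN, ITIH2, IGFBP1 and APOA1 led the list, while APOC3, an apolipoprotein of triglyceride-rich particles, stood at 1.20 ± 0.54 and TTR, the thyroxine carrier transthyretin, at 1.18 ± 0.42 (SD, n = 4 arrays). Of 21 genes of fatty acid oxidation and ketogenesis, 6 were brighter in Cy3 and 0 in Cy5 (10 and 0 adjusted over the list alone), with a median of -0.39. The ketone body dehydrogenase BDH (now BDH1) stood at -1.10 ± 0.07, HADHA, a subunit of the mitochondrial trifunctional protein, at -0.94 ± 0.44, and HADHSC (now HADH) at -0.71 ± 0.12, against -0.13 on a second probe that did not pass. The wells beside HADHSC had ratio profiles at a distance of 0.30 (PEX3) to 0.35 (E4F1) from its own, so part of its ratio may not be its own. ACADS had a mean of 0.50 ± 0.44 and did not pass.

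With camera, these 4 of 37 lists passed. The adjusted p was 3.29e-07 for ribosomal proteins, 0.00018 for fatty acid oxidation, 0.017 for liver-secreted proteins and 0.018 for NK and cytotoxic markers. The rotation test fry called 9, these 4 and red blood cell markers (adjusted p = 0.031) among them. The remaining fry calls were liver function lists with medians toward Cy3. They were gluconeogenesis and glycogen metabolism (fry adjusted p = 0.031), bile acid synthesis and transport (0.040), complement components (0.044), and urea cycle and amino acid catabolism (0.047). Camera called no list of another cell type: among others, T cell markers had a median of 0.22 (camera adjusted p = 0.090), red blood cell markers 0.16 (adjusted p = 0.11), and B cell and plasma cell markers -0.02 (adjusted p = 0.96). The calls of NK markers and liver-secreted proteins were lost without week 32 (adjusted p = 0.051 and 0.053), that of NK markers also with the intensity filter (adjusted p = 0.13) and that of liver-secreted proteins with the trended prior (adjusted p = 0.070). With the series matrix values the calls of liver-secreted proteins and of fatty acid oxidation were lost (adjusted p = 0.32 and 0.061), with medians of -0.997 and -0.841 among values that are not centred. The number of called lists was 10 with median centring, and ranged from 2 without week 32 to 10 without week 21.

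The interferon-stimulated genes, the antiviral genes switched on by interferons, were the first question of an infection time course. Their ratios differed widely between the weeks. ISG15, a ubiquitin-like protein, had a log2 ratio of 2.68 at week 19, -0.65 at week 20, -1.73 at week 21 and 2.79 at week 32. IFI27 had 2.48, -0.68, -1.49 and 2.51, OAS3, which makes the activator of RNase L, had 2.45, 0.37, -1.11 and 2.46, and IFI6 (listed as G1P3) had 2.27, -0.37, -1.65 and 1.78. OAS2 had 1.48, 0.21, -0.28 and 1.20, IFITM1 1.23, 0.59, -0.28 and 1.03, and SP110 (listed as IFI75) 1.32, 0.38, -0.35 and 1.29, with smaller ratios on a second probe (0.22, 0.38, -0.19 and 0.43). The median of the 25 measured members was 0.59, 0.03, -0.33 and 0.63. It lay above all 10000 random lists at weeks 19 and 32, at the percentile 50.6 at week 20 and at 1.71 at week 21.

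Over the 4 arrays together, the median mean ratio of the list was 0.31, and camera did not call it (p = 0.038, adjusted p = 0.11; adjusted p = 0.86 with an estimated correlation). In limma 2 members passed (1 adjusted over the list alone), the nuclear body protein SP100 with 0.71 ± 0.30 (SD, n = 4 arrays; limma adjusted p = 0.024) and IFITM2 with 0.57 ± 0.30 (limma adjusted p = 0.043). IRF9 (listed as ISGF3G) had a mean of 0.31 ± 0.27 and did not pass. Without week 21 the list was called, with a median of 0.42 (camera adjusted p = 0.0058), as it was with array weights (adjusted p = 0.010). With the series matrix values, which are not centred, its median was -0.11, and it was among 3 lists that camera called as higher than the other probes (adjusted p = 0.0091). A separate list of 13 interferon-gamma response genes and chemokines did not share the rise at weeks 19 and 32. Its median was -0.22, -0.16, -0.28 and -0.36 at weeks 19, 20, 21 and 32. The percentiles were 3.78, 10.45, 3.62 and 0.02, and camera did not call that list over the 4 arrays (adjusted p = 0.10).

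**Figure D2:**
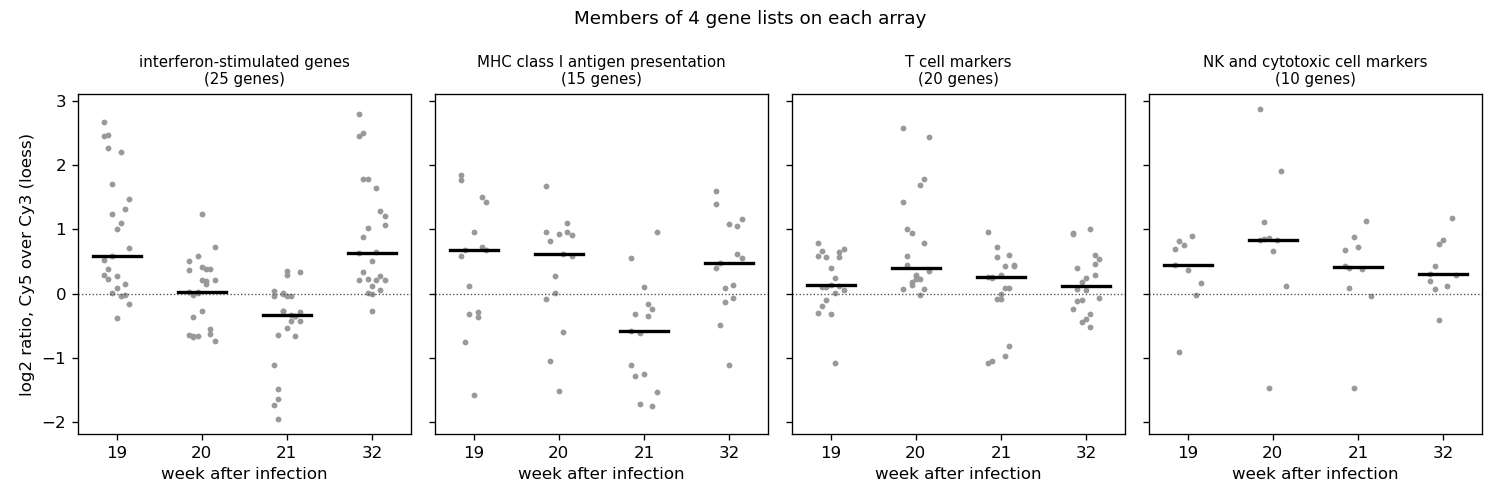
Log2 ratio of Cy5 over Cy3 (y axis) of the members of 4 gene lists on each array, by week after infection (x axis); grey points are genes and black bars the list median. The median of the interferon-stimulated genes is 0.59 at week 19, -0.33 at week 21 and 0.63 at week 32, and that of NK and cytotoxic cell markers is 0.84 at week 20.

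The second comparison set week 32 against weeks 19 to 21. The interferon-stimulated list was higher at week 32, with a median difference of 0.51 in log2 ratio (limma camera adjusted p = 0.0039). It was the single list of 37 that passed. With an estimated correlation its adjusted p was 0.89 and 0 lists passed, and fry called 0. The difference of ISG15 was 2.70 ± 1.63 (SE), that of IFI27 2.41 ± 1.49, that of OAS3 1.89 ± 1.28 and that of IFI6 1.70 ± 1.42, none of which passed limma. The members with the smallest p, ISG20 with 0.97 ± 0.44, IRF7 with 0.65 ± 0.32, PLSCR1 with 0.51 ± 0.27, OAS1 with 0.57 ± 0.31 and SP100 with 0.48 ± 0.30 beside ISG15, did not pass either. IFIT5 (listed as RI58) and IRF9 had differences of -0.38 and -0.12. The list's week 19 median of 0.59 was close to its week 32 median of 0.63, and without week 21 the difference was 0.36 and no longer called (camera adjusted p = 0.12). It was also not called with spots of score 0 kept (adjusted p = 0.12) or with the series matrix values (adjusted p = 0.99).

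For single probes, limma called 0 of 6631 in this comparison, while 143 had an unadjusted p below 0.05, which is 2.16%. The smallest adjusted p was 0.98. None of the genes with the smallest p therefore passed. Below weeks 19 to 21, they were CBLC with a difference of -1.64, CKMT1 with -1.13, MT1H with -1.67, PDCL with -1.10 and CYP17, a steroid hydroxylase, with -0.99. Above weeks 19 to 21, they were IMPA2 with -0.43 at week 32 against -1.63 to -1.14 before, SLC23A2, a vitamin C transporter, with a difference of 0.81, ESRRG with 1.22, ITGA6 with 0.90 (1.93 on a second probe) and MCM2, a subunit of the replicative helicase, with 0.86.

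The arrays were also described one by one, without a test. A ratio of at least 2-fold was seen at 335 probes at week 19 (147 toward Cy5, 188 toward Cy3), 454 at week 20 (216 and 238), 652 at week 21 (202 and 450) and 309 at week 32 (189 and 120). These splits moved with the normalisation: with median centring in place of the loess curve they were 84 and 292 at week 19, 175 and 304 at week 20, 253 and 469 at week 21, and 282 and 83 at week 32. The largest single ratio was that of VTN at weeks 19 and 32 (-3.59 on both), of RPS4Y at week 20 (3.63) and of IGFBP1 at week 21 (-4.47). Across 6488 probes, which are not independent replicates, the ratios of weeks 19 and 32 correlated with r = 0.79, those of weeks 19 and 20 with 0.72 and those of weeks 20 and 32 with 0.60. Week 21 stood further off, with 0.36 against week 19, 0.47 against week 20 and 0.27 against week 32. A shared baseline RNA and the dye preference of single probes would make the ratios correlate without a common change, so these values do not measure one. In the quantile-normalised intensities of 1 channel, week 21 did not stand off, with 0.93 in Cy5 and 0.97 in Cy3 against week 20. Week 32 had the lowest values in Cy3, with 0.91, 0.89 and 0.90 against weeks 19, 20 and 21. Those weeks had 0.95 to 0.97 among each other. Whether the week 32 array shares the baseline RNA of the others was not tested.

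Lists of immune genes also differed between weeks, in a comparison of each week with the other 3 that was chosen after seeing the data. The interferon-stimulated list was higher at week 19, with a median difference of 0.56 (camera adjusted p = 2.24e-06 over 148 tests), as it was at week 32 with 0.51 (adjusted p = 0.0031), and lower at week 21 with -0.73 (adjusted p = 0.00058), so its rise is not particular to week 32; no list passed with an estimated correlation. T cell markers were highest at week 20, with a median difference of 0.53 (camera adjusted p = 7.39e-09; adjusted p = 0.94 with an estimated correlation). Chosen after their values were seen, CD3D, a chain of the T cell receptor complex, had log2 ratios of 0.79, 2.58, 0.97 and 0.92 at weeks 19, 20, 21 and 32, CD8A had 0.58, 1.79, 0.60 and 0.61, and the granzyme GZMA had 0.69, 2.87, 0.67 and 0.31. The median difference of NK and cytotoxic markers at week 20 was 0.55 (camera adjusted p = 0.0096), and endothelial markers were lower that week, with -0.29 (adjusted p = 0.013; both 0.94 with an estimated correlation). Genes of MHC class I antigen presentation were lowest at week 21, with a median difference of -0.89 (camera adjusted p = 0.00011; adjusted p = 0.94 with an estimated correlation). Also chosen after their values were seen, HLA-B had 1.42, 0.91, -1.53 and 1.16 and HLA-C 1.77, 1.68, -1.11 and 1.40, while B2M, the light chain they share, stood at 1.85, 0.96, 0.56 and 1.59. A low ratio at week 21 was not particular to immune genes. Picked in the same way, the repeated clone of beta-actin had 0.91, 1.15, -1.35 and 0.72, and that of ARF3 had 0.22, 0.64, -0.92 and 0.84. Another 10 wells of the repeated-clone plates went the other way, with 0.63 to 1.38 at week 21. The clones of CD8A, HLA-C and HLA-B had ratio profiles close to those of neighbouring wells (CEACAM1, HBG1 and PI3, at a distance of 0.39, 0.41 and 0.43), so part of these values may not be their own. Each such comparison rests on 1 array of the named week.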

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

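In 6 of 97 series of 4 arrays, made of the named genes and the list medians, 1 array lay far from the other 3 by Dixon's criterion, and chance flags about 1 in 20. ITIH2 stood at -0.70 at week 21, against -3.50 to -3.27 on the other arrays. VTN stood at -2.19 at week 21, against -3.59 to -3.41. The median of MHC class I antigen presentation was -0.59 at week 21, against 0.47 to 0.67. GZMA stood at 2.87 at week 20, against 0.31 to 0.69, and IFIT5 (listed as RI58) at 1.24, against -0.54 to -0.27. SLC23A2 stood at 1.97 at week 32, against 1.10 to 1.19. This gene had been named for its week 32 value, so its flag follows in part from that choice. The same holds for GZMA, named for its mean, and for IFIT5, named for its difference at week 32 against the list. The week 20 value contributes to both, so the share of 1 in 20 does not apply to these genes. No explanation was tested for these.

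The 2 tests below of the dye orientation and of the normalisation were chosen after the result was seen. The interferon-stimulated genes were above the Cy3 level at weeks 19 and 32 and not at weeks 20 and 21. A turned dye orientation at weeks 20 and 21 stays open, but a turn alone would not account for week 20. The list median there was 0.03, and its mean was 8.62 in both channels. Turning the sign would change this little and would not give the medians of 0.59 and 0.63 of weeks 19 and 32. Outside the list, the lowest correlation across probes between the week 19 or 32 array and the week 20 or 21 array was 0.28. The dye preference of single probes does not turn with the orientation, so ratios could correlate positively under a turned orientation too. The correlation therefore cannot decide this. A change of the Cy3 RNA alone is argued against as the source over all 4 arrays, since the list mean varied over them 2.60 times as much in Cy5 as in Cy3, with an SD of 0.53 against 0.20. It is not excluded as a part of the week 32 difference: against the mean of weeks 19 to 21, the list mean at week 32 was 0.39 lower in Cy3 and 0.32 higher in Cy5, and its Cy3 value of 8.29 lay below the 8.62 to 8.76 of the other arrays. The loess is also argued against, since with median centring the range of the list median was 117% of its loess value. A change of interferon-stimulated transcripts in the Cy5 RNA between the biopsies, at week 32 with a part in Cy3, may remain as a hypothesis; other differences between biopsies, such as where each was taken, stay open and were not tested.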

How the results depend on the processing

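The number of probes that differ between the channels was 1944 with array weights, 42 against a minimum log2 change of 0.5 and 0 with the series matrix values, and from 33 to 1736 with 1 array left out. Of the named single genes, 1 value of 713 reversed in this comparison and 111 lost the call. The lists called over the 4 arrays numbered 7 with array weights, 10 with median centring, 9 without the repeated-clone plates (an alternative added after seeing the data) and 0 with an estimated correlation, and from 2 to 10 with 1 array left out. The median of the interferon-stimulated list was 0.31 and called with array weights (adjusted p = 0.010), reversed to -0.11 with the series matrix values, where camera called it as higher than the other probes (adjusted p = 0.0091), and lay from 0.11 to 0.42 with 1 array left out. At week 32 against the earlier weeks, the number of called lists was 2 with array weights, 4 with median centring and 0 with an estimated correlation, with spots of score 0 kept or with the series matrix values, and from 1 to 4 with 1 array left out. The interferon difference at week 32 was no longer called at 0.51 with an estimated correlation, at 0.49 with spots of score 0 kept and at 1.25 with the series matrix values, and lay from 0.36 to 0.72 with 1 array left out; no alternative called a single probe there. The 2-fold probes numbered 990 at week 19, 1771 at week 20 and 1538 at week 21 with the series matrix values, 221 at week 19 with a normexp offset of 50 (added after seeing the data), and 417 at week 21 with scale normalisation. IRF9 (listed as ISGF3G) reversed to -0.11 with the series matrix values. At week 32, IRF9 reversed to 0.051 with median centring and to 0.70 with the series matrix values, and IFIT5 (listed as RI58) to 0.094 with the series matrix values, and the latter lay from -0.70 to 0.19 with 1 array left out. The series matrix values are not centred, with an all-probe median of -0.38, -0.62, -0.50 and 0.07 at weeks 19, 20, 21 and 32, against 0.03, 0.02, 0.02 and 0.01 after loess; for the other alternatives the cause was not tested. All other totals of the tests above stayed within 1.5 times, but the part toward Cy5 moved further: over the 4 arrays it fell from 427 to 278 with spots of score 0 kept, at week 21 from 202 to 102 with scale normalisation and to 134 with a normexp offset of 50, and at week 19 from 147 to 84 with median centring, where the part toward Cy3 rose from 188 to 292, and at week 32 it rose from 189 to 369 with the series matrix values. Print-tip loess was not run, since printing blocks were not used here, and without replicate 4 there is no week 32 result. No background column was used, so signal over background gives no limit here. No paired analysis was possible because there is 1 group. Of the 8 sign patterns of the 4 arrays, the real one gave 927 probes and the highest other 0, and so few patterns cannot give a share under 0.05; 1 of them, the real one, reached that count.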

Other observations

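The Y-linked genes below and their tests were chosen after the result was seen, and those of the wells before. Of 14 genes of the oxidative stress and metal response list, 4 were brighter in Cy5 and 0 in Cy3 (4 and 3 adjusted over the list alone). Among those brighter in Cy5 was MT2A, chosen after its values were seen, with a mean log2 ratio of 1.29 ± 0.48 (SD, n = 4 arrays; limma adjusted p = 0.010). The list itself was not called (camera adjusted p = 0.71). Of 14 acute phase genes, 3 were brighter in Cy5 and 3 in Cy3. Chosen after their values were seen, PLA2G2A, a secreted phospholipase, stood at 1.40 ± 0.82, ITIH3 at -1.24 ± 0.50 and ceruloplasmin (CP) at -0.99 ± 0.44.

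RPS4Y, EIF1AY and DBY, 3 Y-linked genes, were brighter in Cy5 on all 4 arrays, with mean log2 ratios of 3.36, 1.38 and 1.33. SMCY was brighter in Cy3, with -0.70, and UTY stood at -0.03. Dye bias of single probes, unrelated to the chromosome, stays open. Without RPS4Y, the mean of the other 4 genes, 0.49, was reached by 0.5% of 10000 random lists of 4 probes matched on intensity. EIF1AY and DBY, which with RPS4Y formed the pattern that prompted the test, carry this mean, so the share is not independent of that choice. SMCY and UTY did not go toward Cy5. RNA of animals of different sex in the 2 channels may be a candidate explanation, as the lowest ratio of RPS4Y was 2.97, but 3 and not 5 of the genes were brighter in Cy5, so the test leaves it open. Cross-hybridisation of the human clones with X-linked copies was not tested; RPS4X stood at 0.04, and EIF1A was brighter in Cy5 on all 4 arrays with 0.55.

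Neighbouring wells shared ratio profiles. On the repeated-clone plates, adjacent wells had a median profile distance of 0.42 in log2 ratio, against a 2.5th percentile of 0.61 in 1000 permutations of the wells. DNA shared between neighbouring wells and spots printed close together would both give this, so the distance does not separate them. At week 21, 10 wells of differently named clones, picked after their values were seen out of a block of 12 neighbours, lay between 0.63 and 1.38, while the 2 left out of the block lay at -1.87 and -0.75, and the 78 wells outside the 10 had a median of -0.18. Placement of genes with like symbols side by side is argued against as the source on the single-copy plates: 175 close adjacent pairs remained without pairs of symbols that share their first 3 letters, against a median of 74 in 1000 permutations of the wells, of which at most 2.5% gave over 88. What links those pairs, such as shared DNA or spots printed close together, was not tested, and a clone's name may then not be its only content. Picked after their values were seen, CD8B1 and SFTPA1, a surfactant protein gene, formed such a pair (0.39), as did MX1 and MACS (0.49). Genes of the results above in such pairs included RPL27A with HK1 (0.17), RPL44 with MSMB (0.23), RPS20 with ONECUT3 (0.34), PDCL with STK29 (0.11) and with APOA2 (0.41), and CD8A, HLA-B and HLA-C.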
